A study of Homo sapiens with 4 samples.

How the data were processed

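The data are 4 ChIP-seq libraries of ARP1 multiple myeloma cells, an immunoprecipitation with an antibody to STAT5A and its input from wild-type cells, and the same pair from YTHDF2 knockdown cells. The groups were taken from the sample labels. The series' design text speaks of histone modifications and the titles call the input RNA, whereas the antibody and molecule labels give STAT5A and genomic DNA, and the latter were followed. Per the labels' protocols, cells were fixed with formaldehyde and sonicated, and the chromatin was pulled down with magnetic beads. The submitters' processing notes name cutadapt, Trimmomatic, FastQC, Bowtie2 and MACS2 and the hg38 assembly, with no versions or settings. The software that assigned peaks to genes is not given in the sources used here. The libraries were not merged, and 1 peak list was made for each condition.

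Each list gives the position, width, summit, fold enrichment, p-value, q-value, annotation class, nearest gene and distance to its transcript start for every peak. The fold enrichment is a linear ratio as deposited by the authors. What the ratio is taken over is not stated, and it was used only to describe, rank or filter peaks within a list. The p-value and q-value per peak are the authors' own on a linear scale, and the largest q-value in both lists is just under 0.05. An exact 0 in the q-value column, found for 586 knockdown and 1087 wild-type peaks, is a value too small for the deposited number format. Coordinates start at 1, as the widths show, and cover chromosomes 1 to 22 and X. The distance to the transcript start is measured from the nearest edge of the peak and is 0 where the peak spans it, and it defines the authors' promoter class within 1 kb exactly. Genes were matched by gene identifier to the RefSeq gene table of GRCh38.p14, which found 15423 of 15465 identifiers in knockdown and 17847 of 17903 in wild type. Gene symbols that had turned into dates (14 knockdown and 26 wild-type peaks) were recovered in this way, and a current symbol is printed where the list gives an older one. Reads and input signal were not analysed here, so depth is unknown and its effect on peak numbers could not be removed.

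Peaks were called shared when they overlapped a peak of the other list by at least 1 bp, and the counts were checked with bedtools 2.31.1. Chance overlap came from 1000 circular shifts within each chromosome. Shares have exact 95% Clopper-Pearson intervals. A gene counted as occupied when a peak credited to it lay within 1 kb of its transcript start by the authors' distance, among the 19970 protein-coding genes of chromosomes 1 to 22 and X. The plan spoke of the summit, but the distance column refers to the peak edge, so the summit distance was run as an alternative. Each of 10 gene lists was placed among 10000 random lists of the same size. Percentiles are given as a description of the libraries, because genes are not replicates. A percentile takes the middle position among the random lists that tie with the list. P-values from the random lists, adjusted except where stated, are printed only where they bear on a call made by percentile. No test between conditions was made, because each has 1 list. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

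The overlap and gene list steps were tested on simulated data. Planted shares of 20, 50 and 80% among 31227 knockdown peaks were recovered as 20.0, 50.0 and 80.0%. The planted peaks were slightly moved copies of wild-type peaks, and the others were placed off them. Recovery was therefore fixed by the construction and checks only the counting of overlaps. Of random gene lists, 98% in knockdown and 97% in wild type fell inside the central 95%, and lists with 21 of 24 planted members were found in 100% of cases. A count of 21 in 24 has nearly the same percentile in every such list, so this result too was fixed by construction. It does not show that smaller excesses, such as 18 of 24, would be found.

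The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names YTHDF2, STAT5A and MAP2K2, up to 4 members of each list with the highest fold in either peak list, the 8 protein-coding genes of highest promoter fold in both lists, in knockdown only and in wild type only, and the 5 peaks of highest fold in each list. Some items that the rule would name are not reported here. Other genes were named after their values were seen where they make up a small count or lack a counterpart in the other list. Alternatives covered stricter q-values (0.01 and 0.001), a fold of at least 5, merging of peaks within 100 bp, other definitions of overlap and of chance, a longer list reduced to the size of the shorter, a 3 kb promoter window, and other ways of crediting peaks to genes. A planned test of the STAT binding motif in the peaks was left out, since no genome sequence was used here.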

Results

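STAT5A binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in ARP1, an established human multiple myeloma cell line. STAT5A is a transcription factor that acts downstream of the JAK kinases, and YTHDF2 is a reader protein that binds N6-methyladenosine (m6A) on RNA and promotes the decay of the bound transcript. Wild-type cells and cells with a YTHDF2 knockdown were compared, each with 1 immunoprecipitated library and 1 input library, 4 libraries in all. The measurements analysed were 2 lists of called peaks, 1 per condition, with a fold enrichment and a q-value for each peak that are the authors' own. With 1 list per condition, the difference has no replicate check, and no p-value between conditions is given. The read depth of the libraries is unknown, since the lists carry no read numbers. Intervals on shares of peaks are exact (Clopper-Pearson) 95% intervals and cover counting error only. Fold values of the 2 lists are set side by side as descriptions, and a difference between them is not a measured change.

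The first question was where STAT5A lay at the genes named by the design and at MAP2K2, which encodes the ERK-activating kinase MEK2 and is the gene this study linked to YTHDF2 and STAT5A. All 3 genes carried a STAT5A peak over a transcript start in both lists. At YTHDF2 (chromosome 1, hg38), the knockdown peak spanned 28736614 to 28737846 with a fold enrichment of 4.92, and the wild-type peak spanned 28736504 to 28737778 with a fold of 12.3. At STAT5A itself (chromosome 17), the peaks spanned 42288093 to 42288876 with a fold of 5.51 in the knockdown list and 42288000 to 42289540 with a fold of 15.3 in the wild-type list. At the MAP2K2 promoter (chromosome 19), they spanned 4123749 to 4124476 with a fold of 5.94 and 4123670 to 4124485 with a fold of 13.5, respectively. A STAT5A peak at YTHDF2 measures chromatin occupancy and not YTHDF2 RNA, so it does not check the knockdown.

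Beyond the promoter, MAP2K2 differed between the lists in the number of peaks along the gene. The knockdown list assigned 3 peaks to MAP2K2 and the wild-type list 13, of which 2 in each list overlapped the other list. These were the promoter peak and a distal intergenic peak beyond the 3′ end of the gene, at 4084060 to 4084649 in knockdown. The other 11 wild-type peaks lay in introns, an exon, the 3′ UTR, downstream of the gene or at internal transcript starts within 1 kb. Their folds, from 3.64 to 5.91, were all below that of the wild-type promoter peak and below the median of the whole wild-type list. The remaining knockdown peak, intronic at 4112209 to 4112452, lay next to a wild-type intronic peak at 4112507 to 4112771 without overlapping it. Of the 19970 protein-coding genes considered, 372 had at least as many wild-type peaks without a knockdown counterpart as MAP2K2. Across the genome, wild-type peaks without a knockdown counterpart had a median fold of 5.09. The ratio of wild-type to knockdown peak numbers was 1.99 on chromosome 19, against 1.77 for all chromosomes. By its 11 wild-type peaks without a knockdown counterpart, MAP2K2 lay at percentile 98.3 of the protein-coding genes, with no scaling by gene length. Such a number was thus not unique to MAP2K2. Whether it exceeded that of genes of like length or peak number was not tested, so the peak numbers neither show nor exclude a loss particular to this gene.

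**Figure D1:**
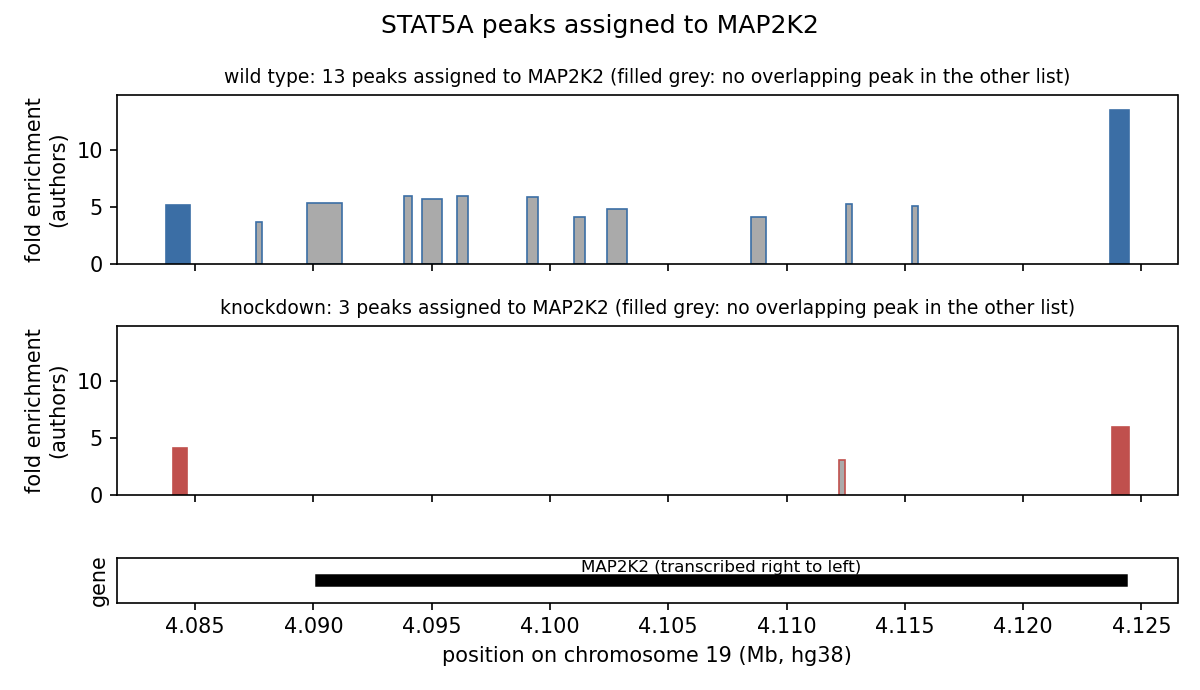
STAT5A peaks assigned to MAP2K2 on chromosome 19 (position in Mb, hg38), with the authors' fold enrichment as bar height and the peak width as bar width; grey bars have no overlapping peak in the other list. The promoter peak at the right end of the gene appears in both lists, while 11 of the 13 wild-type peaks have no overlapping knockdown peak.

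Genome-wide, the knockdown list was the smaller one and, by an overlap of at least 1 bp, most of its peaks overlapped the wild-type list. It held 31227 STAT5A peaks covering 17.7 Mb, and the wild-type list held 55269 peaks covering 38.9 Mb, a ratio of 1.77 in number and 2.20 in covered bases. Among peaks with a fold of at least 5, the ratio in number was 3.70. The median peak width was 419 bp in knockdown and 507 bp in wild type. Of the knockdown peaks, 24081 (77.1%, 95% interval 76.6 to 77.6%) overlapped a wild-type peak by at least 1 bp, and of the wild-type peaks, 22330 (40.4%, 40.0 to 40.8%) overlapped a knockdown peak. After 1000 circular shifts of the peaks along their chromosomes, a mean of 3.10% of knockdown peaks and 1.75% of wild-type peaks overlapped, and no shift reached the observed number. The excess over chance depended on how chance was defined. It was 24.9-fold for knockdown peaks under the shifts, and 2.36-fold when promoter peaks were placed at other transcript starts named in the lists. The shared percentages were 41.3% of knockdown and 23.3% of wild-type peaks when summits had to lie within 100 bp of each other, and 49.6% and 28.0% with a reciprocal overlap of 50%. With the wild-type list reduced to as many top peaks by q-value as the knockdown list holds, they were 67.1% and 61.3%.

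The strongest STAT5A peaks were those found in both lists. All 1133 knockdown peaks with a fold of at least 20 overlapped a wild-type peak, and 5 of the 2552 wild-type peaks with such a fold lacked a knockdown counterpart. Shared knockdown peaks had a median fold of 4.53 and unshared ones 3.95. In the wild-type list the medians were 9.44 and 5.09. When each list was ranked by q-value and divided into 10 equal bins, 99.4% of the top bin of knockdown peaks and 99.7% of the top bin of wild-type peaks were shared. In the last bin the shares were 52.7% and 9.07%.

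**Figure D2:**
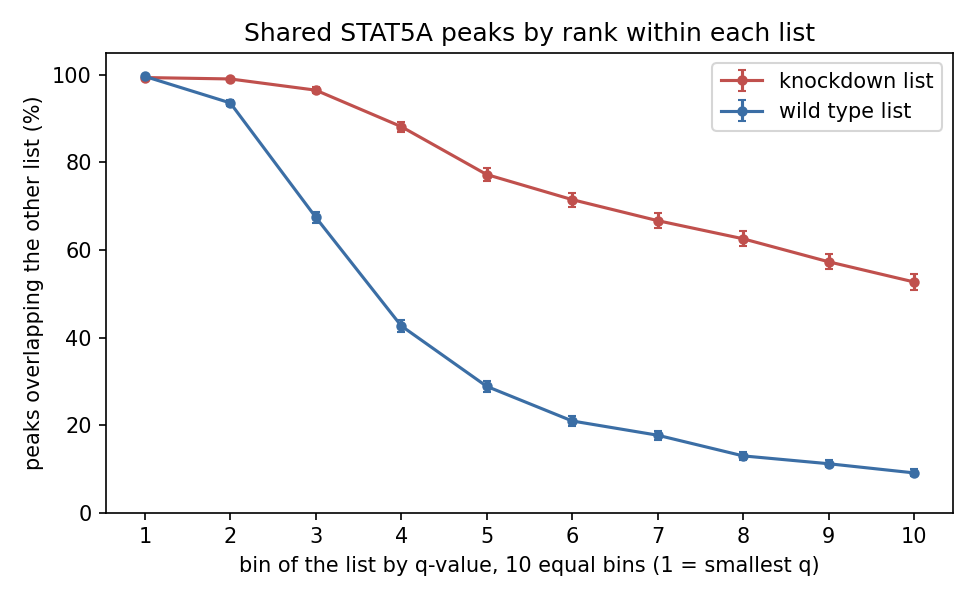
Percentage of peaks that overlap a peak of the other list, by bin of each list ranked by q-value (10 equal bins), with exact 95% intervals that cover counting error only. Both lists start above 99% and end at 52.7% (knockdown) and 9.07% (wild type).

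Of the 5 highest peaks of each list, those at DRAP1, ATXN7L2 and MIR1302-3 were common to both conditions, and all of them overlapped a peak of the other list. DRAP1, which encodes a corepressor of RNA polymerase II transcription, had the highest fold in both lists, 1705.5 in knockdown and 3972 in wild type, at chromosome 11, 65918482 to 65920591 and 65918511 to 65920727. The next knockdown peaks lay at ATXN7L2 (fold 781), MIR1302-3 (771), PXK (515) and PGP (436). The next wild-type peaks lay at DOLPP1 (2372), MIR1302-3 (2034), ATXN7L2 (1777) and LMNTD2 (1716). BAZ2A (402 in knockdown, 1199 in wild type) and ZNF668 (349 and 1519) completed the 8 protein-coding genes with the strongest knockdown promoter peaks present in both lists. Every one of these peaks was annotated to a promoter within 1 kb. Of all knockdown peaks with a fold of at least 20, 94.1% lay within 1 kb of a transcript start, and of such wild-type peaks 92.9%.

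By genomic annotation, promoters within 1 kb took the largest share of STAT5A peaks in both conditions. They held 49.9% of knockdown peaks and 38.9% of wild-type peaks. Distal intergenic regions followed with 21.4% and 22.1%, and introns with 15.4% and 18.2%. Exons other than UTRs held 3.84% of knockdown and 6.28% of wild-type peaks, and 3′ UTRs 1.57% and 3.21%. The direction of this difference depended on which peaks were kept. At q under 0.001 in both lists, promoters held 58.1% of knockdown and 41.5% of wild-type peaks. With the wild-type list reduced to as many top peaks by q-value as the knockdown list holds, its promoter share was 53.4%, above that of the knockdown list.

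**Figure D3:**
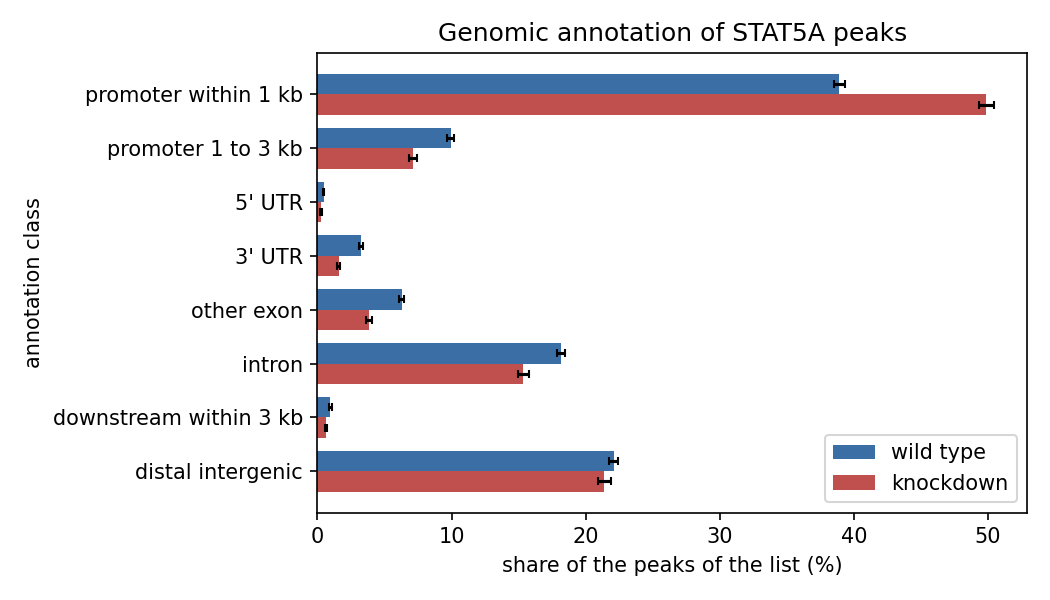
Share of the peaks of each list (percent) in each annotation class of the authors, with exact 95% intervals that cover counting error only. Promoters within 1 kb hold 49.9% of knockdown and 38.9% of wild-type peaks.

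At the level of genes, STAT5A promoter occupancy was largely common to the 2 conditions. A promoter peak within 1 kb was credited to 11196 protein-coding genes in knockdown and to 12912 in wild type. Both lists named 10713 of them, while 483 genes were named in knockdown only and 2199 in wild type only. Independent lists of these sizes would share 7239 if every protein-coding gene were equally likely to be named, which does not hold for all gene families. With the wild-type list reduced to the length of the knockdown list, the numbers in knockdown only and in wild type only were 830 and 1476. Each peak was credited to 1 gene, so a shared peak between neighbouring genes could be credited differently in each list. Of the 483 knockdown-only genes, 261 had a promoter peak that overlapped a wild-type peak, credited to other genes alone in 258 cases, and 222 had none. Of the 2199 wild-type-only genes, 173 had a promoter peak that overlapped a knockdown peak, credited to other genes alone in 117 cases and to the same gene, but not as a promoter peak within 1 kb, in 56, and 2026 had none.

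Most genes with the strongest promoter peaks in a single list had an overlapping peak in the other list. Among the 8 strongest knockdown-only genes, NFYA (fold 109, a subunit of the CCAAT-binding factor NF-Y), TK1 (32.2, thymidine kinase), RTEL1 (25.1), C8orf44-SGK3 (24.5), ARHGAP44 (23.7), GLCCI1 (17.3) and SPRED3 (12.9) lay under a peak that also appeared in the wild-type list. RBMS2 (11.5, an RNA-binding protein gene on chromosome 12, peak 56521522 to 56521950) was the exception. All 8 strongest wild-type-only genes, ZBTB32 (fold 647), AFMID (157), SMIM7 (65.1), SYNGR4 (51.3), CYP39A1 (33.6), PEBP4 (26.7), PJVK (24.9) and SAXO4 (24.2), lay under a peak shared with knockdown. The overlapping knockdown peak was credited to ZBTB32 itself in the first case and to another gene in the others. Genes with no overlapping peak in the other list were singled out after their values were seen. In wild type the strongest of these were PARP2 (20.7, a DNA repair enzyme gene), NEK10 (17.8) and USE1 (16.8), and in knockdown, after RBMS2, PTPN22 (9.62), SLCO1A2 (9.50) and COX7C (8.56).

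For the pathways in which the study placed STAT5A, most promoters were occupied in both conditions, as were 53.6% of those of all protein-coding genes. Of 24 known STAT5 target genes, 18 had a promoter peak in both lists and OSM had one in wild type only (fold 5.47). The strongest were BCL2L1, the gene of the survival protein BCL-XL (fold 91.6 in knockdown, 462 in wild type), CISH, a cytokine-induced inhibitor of JAK-STAT signalling (9.93 and 24), PIM2 (6.48 and 18.9) and SOCS1 (5.25 and 17.0). Of 24 JAK-STAT signalling genes, 20 were in both lists, among them TYK2 (101 and 269), STAT3 (16.3 and 95.6) and IL6ST (16.5 and 92.7), and IFNGR1 and STAT4 were in wild type only. Of 30 genes of the RAS-RAF-MEK-ERK cascade, 26 were in both lists, including HRAS (40.8 and 139), ARAF (59.6 and 78.5), ELK1 (8.38 and 27.3) and KSR1 (6.30 and 25.3). JUN was credited in knockdown only, but its peak overlapped a wild-type peak credited to another gene. Of 21 genes for m6A writers, erasers and readers, 14 were in both lists, among them HNRNPC (57.8 and 51.1), WTAP (5.35 and 24.2), YTHDF1 (4.70 and 16.1) and RBM15B (5.17 and 15.6). HNRNPA2B1 was in knockdown only, under a shared peak. ZC3H13 (fold 5.91) and METTL14 were in wild type only, METTL14 by a peak near the calling threshold (fold 2.68, authors' q-value 0.0327).

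Gene groups of the myeloma cell and of general cell functions gave similar counts. Of 24 plasma cell and myeloma genes, 18 were in both lists, led by SEC11C (14.9 in knockdown, 65.4 in wild type), XBP1, a plasma cell transcription factor (6.46 and 31.6), NSD2 (9.26 and 27.8) and IKZF1 (8.83 and 23.5), and TNFRSF13B was in wild type only. Of 24 cell cycle and replication genes, 20 were in both lists, with MCM5 (55.3 and 278), PCNA (27.3 and 121), MCM7 (21.7 and 96.2) and MKI67 (32.1 and 96.1) in front, CCNE2 in knockdown only, under a shared peak, and CDK4 in wild type only. Of 24 apoptosis genes, 18 were in both lists, led by BCL2L11 (50.4 and 214), BIRC5 (20.7 and 54.4), BBC3 (12.4 and 27.6) and BAD (21.2 and 21.7). BIRC3 was in wild type only, and APAF1, CASP8 and TNFRSF10B in knockdown only, of which CASP8 alone had no overlapping wild-type peak. Of 22 unfolded protein response genes, 17 were in both lists, led by SDF2L1 (173 and 407), CANX (75.2 and 291), MANF (58.0 and 276) and SEL1L (72.8 and 160), and CRELD2 was in wild type only. Of 24 housekeeping genes, 17 were in both lists, led by PPIA (24.6 and 135), PGK1 (24.5 and 114), HSPA8 (8.37 and 36.2) and GAPDH (6.82 and 22.2), with RPL4 and RPL8 in knockdown only and B2M in wild type only. The peaks credited to RPL8 and B2M overlapped the other list.

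Markers of tissues that a myeloma line should not represent had a promoter peak less often than protein-coding genes as a whole, but not rarely. The shares were 21.4% in knockdown and 35.7% in wild type, against 56.1% and 64.7% of all protein-coding genes. Of the 28 markers, 5 had a promoter peak in both lists, 1 (HBB) in knockdown only and 5 in wild type only, among them CD14, GFAP, INS and TNNT2. Examples with high folds were SYN1 (6.40 and 28.4), COL1A1 (3.76 and 11.5) and NEUROG2 (6.72 and 9.37). Against 10000 random lists of the same size from the 19970 protein-coding genes, the share of these markers lay at percentile 0.010 in knockdown and 0.075 in wild type. Against random lists from genes with a promoter peak in either list, it lay at 1.12 in knockdown and, inside the central 95%, at 19.7 in wild type.

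In the same placement, the RAS-RAF-MEK-ERK cascade (percentiles 100 in knockdown and 99.7 in wild type), JAK-STAT signalling (99.6 and 99.8) and cell cycle genes (100 and 99.4) lay above the central 95% of random lists in both conditions. Apoptosis (99.9 and 93.1), unfolded protein response (97.8 and 95.7) and housekeeping genes (98.9 and 85.4) lay above it in knockdown and inside it in wild type. STAT5 targets (96.8 and 92.9), plasma cell genes (96.8 and 93.0) and m6A genes (91.5 and 85.9) lay inside it in both, except that plasma cell genes lay above it in knockdown (98.3) with a 3 kb promoter window. With random lists drawn from genes with a promoter peak in either list, which compares the lists with each other, the knockdown shares of apoptosis, unfolded protein response and housekeeping genes lay inside the central 95% (94.1, 89.3 and 92.0), and the wild-type share of apoptosis genes lay just below it (2.32). In that comparison JAK-STAT signalling (81.5 in knockdown and 77.6 in wild type) and cell cycle genes (93.7 and 36.6) also lay inside it, and the RAS-RAF-MEK-ERK cascade lay above it in knockdown (99.6) and inside it in wild type (44.7). These percentiles describe the 2 libraries and not the conditions. Against random lists from all protein-coding genes, 2-sided p-values adjusted for 20 tests made some of the knockdown calls weak. They were 0.121 for unfolded protein response and 0.072 for housekeeping genes, against 0.0112 for apoptosis genes. For unfolded protein response the p-value from the random lists was already 0.0668 before adjustment. Its knockdown call, and so its difference from wild type, depends on how tied random lists are placed. With every transcript start named in either list counted, an alternative chosen after the data were seen, 7 of the 10 lists lay above the central 95% in each condition, STAT5 targets among them at 99.5 in knockdown and 98.7 in wild type. The wild-type percentiles of apoptosis (98.7), unfolded protein response (99.4) and housekeeping genes (99.7) were then above it too, so that these 3 groups no longer differed between the lists in this call.

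Members without a credited promoter peak were not all free of STAT5A. Of the 48 such members over the 10 lists, 20 had a knockdown peak and 22 a wild-type peak within 1 kb of an end of the gene that was credited to another gene. The peak at SOCS2 was credited to SOCS2-AS1 (fold 5.09 in knockdown, 13.2 in wild type), that at MAP2K1, the gene of the kinase MEK1, to TIPIN (5.25 and 17.2), and that at HSP90B1 to MIR3652 (72.7 and 192). The plasma cell genes TNFRSF17, JCHAIN, SLAMF7 and FCRL5, the kinase cascade genes NRAS and ETS1, and the STAT5 targets IL2RA and LTA had no peak at either end in either list.

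**Figure D4:**
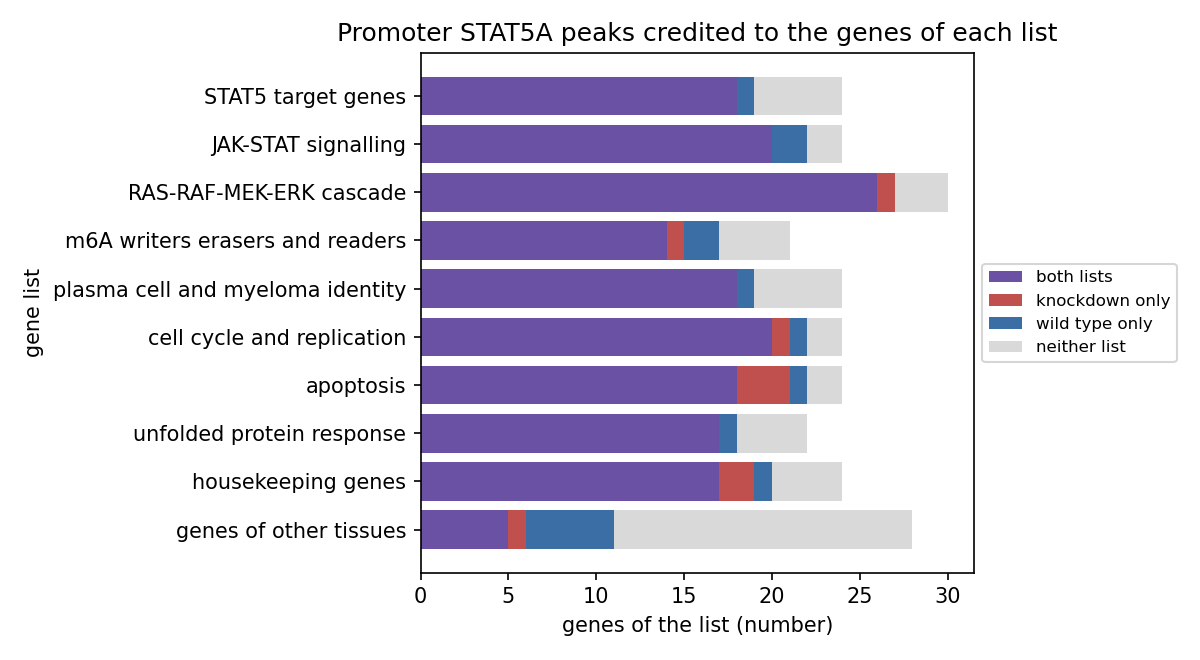
Number of genes of each list with a promoter peak within 1 kb credited to them in both peak lists, in knockdown only, in wild type only or in neither. Most genes of 9 lists fall in the class of both peak lists, against 5 of 28 for genes of other tissues. Of all protein-coding genes, 53.6% fall in that class.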

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

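The 4 alternatives on crediting peaks to genes by summit, by any transcript start or by lack of an overlapping peak were chosen after the data were seen, and the others were planned. The ratio of wild-type to knockdown peak numbers stayed above 1 throughout and was 1.87 at q under 0.01, 2.06 at q under 0.001 and 3.70 at a fold of at least 5. The last value depends on the fold scales of the lists, which may not be alike. The restriction to chromosomes 1 to 22 and X and the merging of peaks within 100 bp removed nothing. The shared percentage was 49.6% of knockdown and 28.0% of wild-type peaks with a reciprocal overlap of 50%, and 41.3% and 23.3% with summits within 100 bp, both stricter by construction. It was 78.9% and 39.4% at q under 0.01 in both lists, 82.5% and 37.7% at q under 0.001 in both lists, 83.7% and 44.2% at q under 0.001 against the full other list, and 67.1% and 61.3% with the longer list reduced to the size of the shorter. Placement within the same annotation class left the observed overlap 2.36-fold above chance for knockdown and 2.17-fold for wild type, since promoter peaks then land on transcript starts that the lists name. The promoter share was 58.1% in knockdown and 41.5% in wild type at q under 0.001, a difference of -16.6 points. With the wild-type list reduced in length its share was 53.4%, and the difference reversed to 3.50 points above knockdown, by the construction of keeping its strongest peaks. Genes named in knockdown only numbered 830 with the longer list reduced, 199 with any transcript start and 222 without an overlapping wild-type peak. The gene lists above the central 95% of random lists numbered 1 in knockdown and 0 in wild type when random lists came from genes with a promoter peak in either list, and 7 in wild type when any transcript start counted. The ratio of shared to unshared median strength was 1.21 in knockdown and 1.94 in wild type with summits within 100 bp, and 1.96 and 3.70 on the minus log10 q scale. Where the construction of an alternative does not show it, the cause was not tested. The other 28 of 60 values for these results moved less than their interval or by under 1.5 times. Of 80 placements of single gene lists under alternatives, 16 crossed a limit of the central 95%. The STAT motif test and its 4 other settings were not run, because no genome sequence was used here. No paired analysis was possible because each condition has 1 peak list, and for the same reason no library could be left out. Read depth is unknown, and whether it limited the smaller list was not tested.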

Other observations

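All tests in this part were chosen after the peak lists had been seen. The rules of 2 of them, on genes of the G2 and M phases and on the strength of knockdown-only promoter peaks, were fixed before their own results were seen. The latter was read with a further q-value condition that its rule did not hold. Gene families differed in how far their promoters were occupied. Of 517 zinc finger genes, 372 (72.0%) had a STAT5A promoter peak in knockdown and 420 (81.2%) in wild type, against 56.1% and 64.7% of all protein-coding genes. Of 83 ribosomal protein genes, 62 (74.7%) were occupied in knockdown and 60 (72.3%) in wild type. Olfactory receptor genes had 2 and 4 occupied promoters of 392. Occupied promoters numbered 4 of 55 in knockdown and 18 of 55 in wild type for keratin genes, 57 and 77 of 96 for potassium channel genes, 233 and 284 of 386 for solute carriers, 38 and 45 of 94 for histones and 24 and 29 of 40 for HOX genes. The lists are of unequal length, and no difference between families was tested. Of 443 tRNA genes, 41 overlapped a knockdown peak and 60 a wild-type peak, 31 of them in both.

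MAP2K2 was among many genes with several wild-type peaks that had no knockdown counterpart. Its 11 such peaks put it at percentile 98.3 of protein-coding genes, where the median gene with any had 2. The highest numbers lay at MAD1L1 (91 such peaks, beside 78 knockdown peaks), INPP5A (78, beside 47) and HDAC4 (77, beside 14). RXRA, a nuclear receptor gene, had 48 beside 3 knockdown peaks. By chromosome, the ratio of wild-type to knockdown peaks ran from 1.29 on chromosome 18 to 2.22 on chromosome 16.

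The knockdown list was smaller, and 77.1% of its peaks overlapped a wild-type peak by at least 1 bp, against 49.6% with a reciprocal overlap of 50% and 41.3% with summits within 100 bp. Complete loss of the peak at a distinct set of the strongest sites was argued against, since 0.196% of wild-type peaks with a fold of at least 20 lacked a knockdown peak. For folds from 10 to 20 a complete loss stays open, since 9.07% of 8456 wild-type peaks lacked a knockdown peak, but these had a lower median fold (11) than the shared ones (12.8). Partial loss could not be seen in this way at any fold, because a site overlapped by any called knockdown peak counts as kept. Weaker enrichment or lower depth of the knockdown library is a candidate explanation, because the top bin of 10 bins of wild-type peaks by q-value was 99.7% shared and the shares fell steadily with rank. Lower STAT5A occupancy at most sites after YTHDF2 knockdown would give the same picture, and the ratio of 1.77 in peak numbers cannot be told apart from a difference between libraries with 1 library per condition.

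Among the genes of the 1000 strongest peaks of each list by fold, unfolded protein response genes held 8 of 17 occupied members in knockdown and 7 of 18 in wild type (percentile 100 of random occupied genes in both), and cell cycle genes 5 of 21 in each (98.7 and 99.3). Sterol synthesis enzymes held 5 of 13 and 6 of 14, a list made because HMGCS1 was seen there, so that its placing tests nothing. STAT5 targets held 1 of 18 occupied members in knockdown (5.56%) and 1 of 19 in wild type (5.26%), BCL2L1 in both, at percentile 45.6 at most. All genes with a promoter peak held 7.77% and 6.75%, so known STAT5 targets were not over-represented among the strongest peaks. Housekeeping genes, a proxy for the most transcribed promoters, lay at 76.1 at most. Selection of known STAT5 target promoters and a signal following the most transcribed promoters both stay open. Lists this short cannot fall below the central 95%: the plasma cell list, with 0 of 18 in knockdown, lay at 11.6. For another factor acting on CCAAT-box promoters, a list of G2 and M phase genes lay at percentile 99.9 in knockdown, but at 93.5 in wild type, inside the central 95%. Cell cycle genes had already been seen among the strongest peaks. The list therefore cannot tell such a factor from any other cause shared by cell cycle promoters. A factor on CCAAT-box promoters too stays open, since no sequence was searched for the STAT or CCAAT motif. A role of STAT5A itself at these promoters was not tested.

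The genes with a promoter peak in knockdown only were weighed against 2 explanations. A shared peak credited to a neighbouring gene is a candidate explanation for 53.4% of the 483 genes. For the 222 with no overlapping wild-type peak, peaks near the calling threshold may account for some. The rule fixed beforehand, on fold alone, was met: 78.8% had a best promoter fold under 4.83, the median of knockdown promoter peaks. Of genes in both lists, 39.5% did. A condition on the q-value was not part of that rule and was not met, as 25.7% had a best q-value of 0.001 or more, against 5.32% of genes in both lists. With that condition the explanation stays open. A gain of STAT5A at the few stronger ones, such as RBMS2, was not tested for lack of replicates.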
